A study of Rattus norvegicus with 6 samples.

How the data were processed

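Renal cortex of 6 male Sprague-Dawley rats was profiled, 3 given corn oil (vehicle) and 3 given sulfone bis(p-chlorophenyl) in daily doses of 250 mg/kg for 4 weeks. The rats were 5 weeks old at purchase. Per the labels' protocols, total RNA was labelled with Cy3 and each sample was hybridised alone to a 1-colour Agilent rat array. Per the file headers, the spot intensity values on a linear scale were extracted by the authors with Agilent Feature Extraction 10.7.1.1, which subtracts background and writes a processed signal per spot. The submitters' processing notes name version 10.7 of the same software. Groups and replicate numbers were taken from the labels.

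The series table deposited by the authors holds linear intensity values for the same arrays. Set against the scanner files, each column was close to the processed signal divided by that array's 75th percentile, with a log2 correlation above 0.99 across probes for every array. The values were not identical: with them 8350 probes had an unadjusted limma p under 0.05, against 8377 with the values analysed here. Column medians were 0.11, 0.108 and 0.109 for vehicle 1 to 3 and 0.109, 0.105 and 0.105 for treated 1 to 3. Every column of values belonged to a known sample.

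Values analysed here were log2 of the processed signal minus the array's 75th percentile over 61537 non-control probes. No probe was saturated. Probes with an outlier flag on any array (11) were left out. A probe was tested when it was well above background on all 3 arrays of at least one group, which left 40643 probes. Probe accessions were matched without versions to a RefSeq gene table of assembly GRCr8: 28206 probes had 1 symbol, 33331 had none and 0 had several. The tested set covered 12118 genes, and a gene with several probes was represented by the one with the highest mean signal.

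Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Before the data were examined, 41 gene lists were fixed and were tested with camera at a preset inter-gene correlation of 0.01 against all other tested genes, adjusted over the lists. Member counts are given adjusted over all probes and adjusted over the list alone. Where a group had no array well above background, the difference is given as a lower bound, set against the per-array floor of signals well above background or the probe's own value, whichever was higher. The number of arrays, 3 per group, limits the precision.

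The rule for named genes was fixed before the data were examined. Because fewer than 10 probes passed, it took the 8 highest and 8 lowest genes by log2 fold change with an unadjusted p under 0.01 whose groups did not overlap and which were well above background in the brighter group. It also took up to 4 called members of each list, or the 2 with the largest absolute change where none was called, and 9 fixed genes. Other members are named because they passed adjusted over their list alone or because of their tissue of origin, and these were chosen after their values were seen.

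Slides and scans divided the arrays unevenly: slide 1 and scan 1 held vehicle 1 to 3 and treated 1, and slide 2 and scan 2 held treated 2 and 3. With slide as a fixed block, the estimate is treated 1 against the 3 vehicle arrays, since slide 2 holds 1 group only. Alternatives covered background correction, normalization, the filter on dim probes, slide and replicate number as blocks, the variance model, the source of the values, each array left out, set tests and thresholds. Among the set tests, fry asks whether a list changed at all, whereas camera asks whether it changed more than other genes. A call held or lost with fry thus answers a different question. A floor on dim values, a looser threshold and a liver transcript score as a covariate were added after seeing the data. The planned normexp correction used the median spot signal in place of the mean.

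The probe test was tested on simulated data with the real probe means and spreads, independent noise and 200 changed probes among 40643. It called 58% of probes changed by 1 on the log2 scale, 82% of those changed by 2, 94% of those changed by 3 and 98% of those changed by 4, with 10 unchanged probes called. Changed probes were drawn at random and no slide difference was simulated, so these shares do not describe probes that vary strongly between arrays. Cyp2b2, at a real log2 fold change of 4.12 with a treated SD of 1.56, was not called. In gene lists simulated with independent genes, the list shifted by 0.5 on the log2 scale was called and 0 of the others were. Independent genes cannot show false calls that come from members varying together. In the real data the estimated correlation within the cell division list was 0.61.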

Results

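The data comprised 6 arrays of rat renal cortex, 3 from vehicle-treated animals and 3 from animals given sulfone bis(p-chlorophenyl), a chlorinated diaryl sulfone. Between 66.1% and 68.2% of the non-control probes of an array were well above background. The 75th percentile of processed signal ranged from 910.3 to 1101 across arrays, and array pairs correlated across probes at 0.982 to 0.994 (Pearson's r over tested probes, which are not independent replicates). The comparison addressed how repeated dosing altered transcript levels in the cortex.

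Dhcr7, the enzyme of the last step of cholesterol synthesis, rose in treated cortex, and the potassium channel gene Kcna4 and 1 probe of the single-strand DNA binding gene Nabp1 fell. Dhcr7 had a mean log2 signal of 2.16 ± 0.04 (SD, n = 3) in vehicle and 3.56 ± 0.08 (SD, n = 3) in treated arrays, a log2 fold change of 1.40 (SE 0.08, limma adjusted p = 0.025), and 1.49 with slide as a block. Kcna4 was at least 1.64-fold lower (limma adjusted p = 0.0039) and was not well above background on any of the 3 treated arrays. The dim Nabp1 probe was at least 2.16-fold lower (limma adjusted p = 0.018), while the brighter Nabp1 probe had a log2 fold change of -1.06 with an adjusted p of 0.066. In total 1 probe was called higher and 2 lower among 40643, whereas 8377 (20.6%) had an unadjusted p under 0.05, of which 3400 were higher and 4977 lower. The groups did not overlap for 28.4% of tested probes, against the 10% that chance gives for 3 against 3. With slide as a fixed block 0 probes were called higher and 1 lower, and the 3 probes named here were not among the calls. The Dhcr7 call also ended without any 1 array other than treated 1, at log2 fold changes of 1.39 to 1.44. It ended at 1.40 with the replicate block, without a filter, with only probes above background on all arrays, with a floor on dim values and with the liver score. The Kcna4 call ended without vehicle 2 or treated 2, with the replicate block, with normexp (-0.40) and with a floor on dim values (-0.71). The Nabp1 call ended without vehicle 1, vehicle 2, treated 2 or treated 3, with the replicate block, without a filter and with a floor on dim values. The p-values of Kcna4 and the dim Nabp1 probe belong to fitted differences (-2.72 and -3.15) that rest on treated values not well above background.

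**Figure D1:**
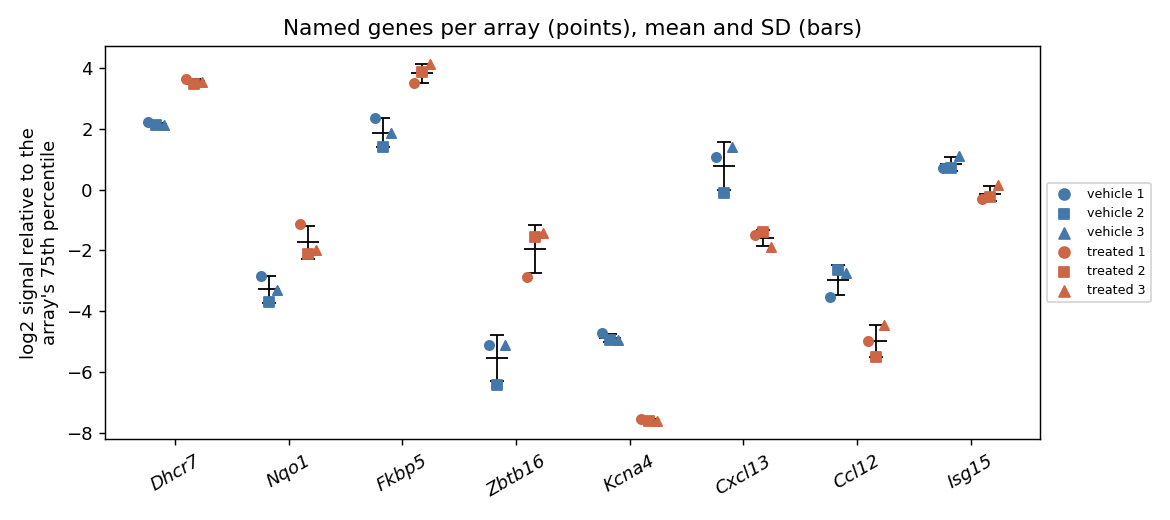
Log2 signal relative to the array's 75th percentile for 8 named genes, with 1 point per array, the group mean as a horizontal mark and the SD as bars (n = 3 per group). Dhcr7 lay between 2.13 and 2.21 in vehicle and between 3.48 and 3.65 in treated arrays, and Kcna4 was not well above background on any treated array.

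The highest differences lay in cytochrome P450 and glucuronosyltransferase genes that the nuclear receptors CAR and PXR control in liver. A picked set of liver transcripts, defined below, varied together between the same arrays. Cyp2b1 was at least 17.8-fold higher, Cyp2b21 at least 22.3-fold, Cyp2b12 at least 15.2-fold and Ugt2b1 at least 10.01-fold, each without any vehicle array well above background, and their adjusted p-values over all probes lay between 0.081 and 0.099. Cyp3a23-3a1 had 1 vehicle array well above background, so its fitted log2 fold change of 6.29 (SE 1.14, adjusted p = 0.098) rests on values below background, and with dim values at the floor it was 5.56. Cyp2b2 had a log2 fold change of 4.12 (SE 0.74, adjusted p = 0.097). Of the 20 tested CAR and PXR targets, 9 were higher adjusted over the list alone and 0 adjusted over all probes. Those 9 included Por, the electron donor of P450 enzymes (log2 fold change 1.08, SE 0.23), and Gadd45b (0.83, SE 0.16). The list had a median log2 fold change of 1.55 and a camera adjusted p of 1.39e-05, and the median was the same with dim genes at their bounds. The call was lost at adjusted p = 0.46 with an estimated correlation and at adjusted p = 0.13 with the set test fry. Without treated 3 the median was 1.02. The list median was 0.67 with slide as a block, and 0.34 on slide 1 alone with the brightest probes chosen on that slide, and the call held in both. Probes of the Cyp2b and Cyp3a families can bind each other's transcripts, so the identity of the single members is uncertain.

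Albumin mRNA (Alb), the most abundant liver transcript, had log2 signals of 3.49, 2.43 and -0.28 in vehicle 1, 2 and 3 and of 1.26, 2.12 and 3.92 in treated 1, 2 and 3. Ttr, which encodes transthyretin, had 3.12, 1.97 and -0.90 in the vehicle and 0.76, 1.55 and 3.70 in the treated arrays. Cyp2b1 had -3.31, -1.67 and 0.43 in treated 1, 2 and 3, and Cyp3a23-3a1 had -1.24, 0.08 and 2.19. In the vehicle arrays Cyp3a23-3a1 had -4.48, -5.56 and -7.79, with 1 of the 3 arrays well above background. Cyp2b2, well above background on all 3, had -2.02, -2.28 and -2.30. Of 29 tested liver transcripts, 17 were picked because vehicle 1 exceeded vehicle 3 by over 1. Some of the rest, among them Apob, Apoh and F2, ran the other way, higher in vehicle 3 than in vehicle 1. The pick did not use the treated arrays, where each of the 17 was higher in treated 3 than in treated 1, by 1.15 to 3.44. The median excess of treated 3 over treated 1 was 2.66 for these 17. It was 3.74 for Cyp2b1, 3.10 for Cyp2b2 and 3.14 for Ugt2b1, but 0.92 for Por and 0.05 for Gadd45b. Of the 20 CAR and PXR targets, 10 moved with the liver transcripts by over 0.5 log2 per log2 unit, in a slope pooled within both groups. Vehicle 1 exceeded vehicle 3 by a median of 3.05 over the 17 liver transcripts. Among P450 members well above background on all arrays, this difference was 2.83 for Cyp2b3, 4.05 for Cyp3a2 and 3.52 for Cyp2c7, but 0.28 for Cyp2b2. The slopes of Cyp2b2 and Cyp2b1, both among the 10, thus came largely from the treated arrays. Whether the P450 and Ugt2b1 signal came from kidney or liver cells was not resolved by these arrays.

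**Figure D2:**
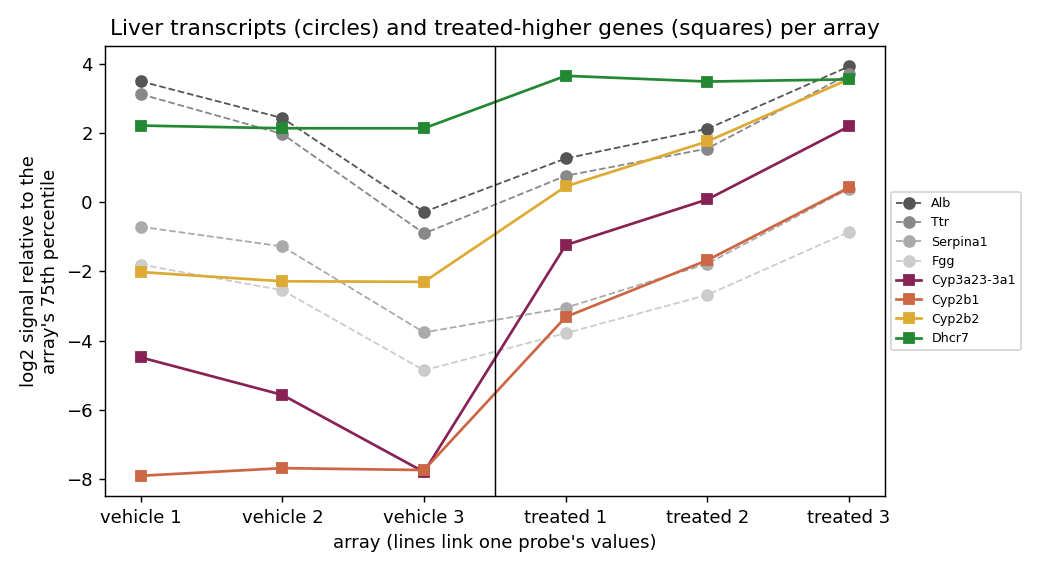
Log2 signal relative to the array's 75th percentile on each of the 6 arrays for 4 liver transcripts (circles, dashed lines) and 4 genes higher in treated arrays (squares, solid lines), 1 probe per line. Alb ranged from -0.28 to 3.92 and was high in vehicle 1 as well as in treated 3, and the treated values of Cyp2b1, Cyp2b2 and Cyp3a23-3a1 followed the same order of arrays while Dhcr7 did not.

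Genes controlled by the antioxidant regulator NRF2 were higher as a group. Of 37 tested members, 13 rose adjusted over the list alone and 0 adjusted over all probes, with a median log2 fold change of 0.44 and a camera adjusted p of 1.59e-09. This call was lost at adjusted p = 0.40 with an estimated correlation. Nqo1, a quinone reductase, had a log2 fold change of 1.54 (SE 0.33), Gstp1, a glutathione transferase, of 1.30 (SE 0.22), and Me1, which supplies NADPH, of 0.89 (SE 0.11). Hmox1, which encodes heme oxygenase, had 2.18 (SE 0.63) but only 0.79 with slide as a block, and treated 3 exceeded treated 1 by 2.51. The list median was 0.32 with slide as a block, where the call held. One of the 37 members moved with the liver transcripts by over 0.5 per log2 unit. Cyp1a1, the usual target of the aryl hydrocarbon receptor (AhR), was not well above background on any array. The 7 tested AhR targets were not called (median 0.23, camera adjusted p = 0.099), though 2 of them, Nqo1 and Ugt1a6, rose adjusted over the list alone. This list was called with slide as a random block (0.26) and with fry, and its median was 0.31 with slide as a fixed block.

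Among 15 conjugating enzymes, 5 were higher adjusted over the list alone and 0 adjusted over all probes. The list median was 0.60 with a camera adjusted p of 0.00039, lost at adjusted p = 0.37 with an estimated correlation, and 0.64 with slide as a block. Besides Ugt2b1 these were Sult1a1 (1.07, SE 0.24), Ugt1a1 (0.74, SE 0.12), Ugt1a2 (0.67, SE 0.10) and Ugt1a6 (0.56, SE 0.09). Ugt1a probes can bind a shared part of the transcripts, so these 3 are not independent measurements.

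Interferon-responsive and chemokine genes were lower. Of 25 interferon response genes, 11 fell adjusted over the list alone and 0 adjusted over all probes, including Gbp2 (-0.97, SE 0.10) and Isg15 (-0.98, SE 0.17). The median log2 fold change was -0.49 (camera adjusted p = 1.59e-09), lost at adjusted p = 0.40 with an estimated correlation. Of 22 chemokines and cytokines, 9 fell adjusted over the list alone and 0 adjusted over all probes, including Cxcl10 (-1.29, SE 0.14), Ccl2 (-1.39, SE 0.23) and the B cell attractant Cxcl13 (-2.38, SE 0.40). Their median was -0.44 (camera adjusted p = 2.17e-05), lost at adjusted p = 0.37 with an estimated correlation. With slide as a block the medians were -0.51 and -0.60 and both calls held.

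Markers of macrophages (median -0.31, camera adjusted p = 0.030) and lymphocytes (median -0.32, camera adjusted p = 0.014) were also called lower, at adjusted p = 0.67 and adjusted p = 0.63 with an estimated correlation. Against the mean of the other 2 vehicle arrays, vehicle 2 had medians of -0.32 and -0.26 for these lists, about the size of the group differences. Against the mean of all vehicle arrays, the baseline of the treated values that follow, vehicle 2 had -0.21 and -0.17. Treated 1, 2 and 3 had -0.07, -0.44 and -0.37 for macrophages and 0.02, -0.46 and -0.51 for lymphocytes against the mean of the vehicle arrays. Of 22 macrophage genes 2 fell adjusted over the list alone, Fcgr3a (-0.99, SE 0.17) and the scavenger receptor Msr1 (-1.80, SE 0.33, well above background on 2 treated arrays), and of 20 lymphocyte genes 0 did. With slide as a block the medians were -0.07 and 0.02 and both calls ended. The macrophage call also ended without vehicle 1, vehicle 3, treated 2 or treated 3 (medians -0.25 to -0.23), and the lymphocyte call without vehicle 1, treated 2 or treated 3 (-0.28 to -0.20). Both calls ended with slide as a random block (-0.18 and -0.21), the lymphocyte call ended with normexp (-0.17), and the macrophage call ended with only probes above background on all arrays (-0.25) and with the liver score as a covariate (-0.25). Both also ended with fry. Among other genes of the named-gene rule, Ccl12 had a log2 fold change of -2.02 (SE 0.35) and Marchf11 of -1.77 (SE 0.31), each with an adjusted p of 0.096, and Fzd9 was at least 2.42-fold higher (adjusted p = 0.083). Rgs18 was at least 2.21-fold, Ppp1r17 at least 1.77-fold and Gpr84 at least 1.44-fold lower, with adjusted p-values from 0.108 to 0.146. The 33 cell division genes had a median of -0.47, or -0.43 with 1 dim gene at its bound, with 0 members passing adjusted over the list alone. Their camera adjusted p was 0.00082, lost at adjusted p = 0.63 with an estimated correlation, and with slide as a block the median was -0.22 and the call ended. Against the mean of all vehicle arrays, the medians were -0.22, -0.22 and -0.95 in treated 1, 2 and 3 and -0.17 in vehicle 3. Against the other 2 vehicle arrays, vehicle 3 had -0.26. The size of the group difference thus rested largely on treated 3, without which the list median was -0.23 and the call held.

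Fatty acid oxidation and synthesis, gluconeogenesis and amino acid catabolism lists were called higher, with small medians and most members not passing. The 24 cholesterol synthesis and uptake genes were not called (median 0.07, camera adjusted p = 0.057, and -0.005 with slide as a block), with Dhcr7 higher and 1 other member, Mvd (-0.36), lower adjusted over the list alone. Of 46 fatty acid oxidation genes, 10 rose adjusted over the list alone and 0 adjusted over all probes, among them Ppara (1.03, SE 0.08) and the lipid droplet gene Plin2 (1.16, SE 0.20). The median was 0.21 (camera adjusted p = 1.76e-07), lost at adjusted p = 0.46 with an estimated correlation, and 0.09 with slide as a block. Of 20 fatty acid and triglyceride synthesis genes, 4 rose adjusted over the list alone, led by Fasn, fatty acid synthase (1.73, SE 0.21, adjusted p = 0.064 over all probes). Their median was 0.21 (camera adjusted p = 0.0034, lost at adjusted p = 0.46 with an estimated correlation), and 0.01 with slide as a block, where the call ended, and the median was 0.39 without treated 1. Of 16 gluconeogenesis and ammoniagenesis genes, 5 rose adjusted over the list alone, including the glutamine transporter Slc38a3 (1.93, SE 0.15) and G6pc1 (0.71, SE 0.17). That list's median was 0.21 (camera adjusted p = 6.22e-05, lost at adjusted p = 0.46 with an estimated correlation) and 0.06 with slide as a block, and it was 0.32 without treated 1 and 0.10 without treated 3. Amino acid catabolism had 10 of 37 members higher adjusted over the list alone, a median of 0.18 (camera adjusted p = 0.00013, lost at adjusted p = 0.46 with an estimated correlation) and 0.08 with slide as a block.

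Glucocorticoid-responsive genes had a median of 0.49 (camera adjusted p = 0.00013, lost at adjusted p = 0.46 with an estimated correlation) and 0.49 with slide as a block. The vehicle arrays disagreed: against the mean of the other 2 vehicle arrays, vehicle 1 had a median of 0.79, vehicle 2 of -0.36 and vehicle 3 of -0.18. Against the mean of all vehicle arrays, vehicle 1 had 0.53 and treated 1, 2 and 3 had 0.49, 0.54 and 0.70. On this shared baseline vehicle 1 lay above treated 1 and just below treated 2. Without vehicle 1 the list median was 0.83. Of 16 members, 3 rose adjusted over the list alone, Fkbp5 (1.96, SE 0.27), Zbtb16 (3.60, SE 0.52, with 2 vehicle arrays well above background) and Klf9 (0.37, SE 0.07), and 0 adjusted over all probes. Genes with male-biased expression in rat kidney had a median of 0.53 (camera adjusted p = 0.0028, lost at adjusted p = 0.40 with an estimated correlation) and 0.70 with slide as a block, with 3 members higher and 1 lower adjusted over the list alone. Of its 14 tested members, 3 (Slc22a7, Slc7a13 and Slco1a1) belong to the straight proximal tubule (S3), and without them the median was 0.26. A set of 11 S3 genes, chosen after the data were seen, had medians of -0.58, -0.34 and 0.28 in vehicle 1, 2 and 3 and of 0.78, 0.05 and 0.51 in treated 1, 2 and 3, relative to each gene's mean over the arrays. Proximal tubule transporters had a median of 0.27 (camera adjusted p = 0.0025, lost at adjusted p = 0.46 with an estimated correlation), with 5 of 46 higher adjusted over the list alone, including the glucose transporter Slc2a2 (0.76, SE 0.12). Of the 46, 5 were S3 genes, and without them the median was 0.23. The list median was 0.17 without treated 3, and 0.12 with slide as a block, where the call ended.

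**Figure D3:**
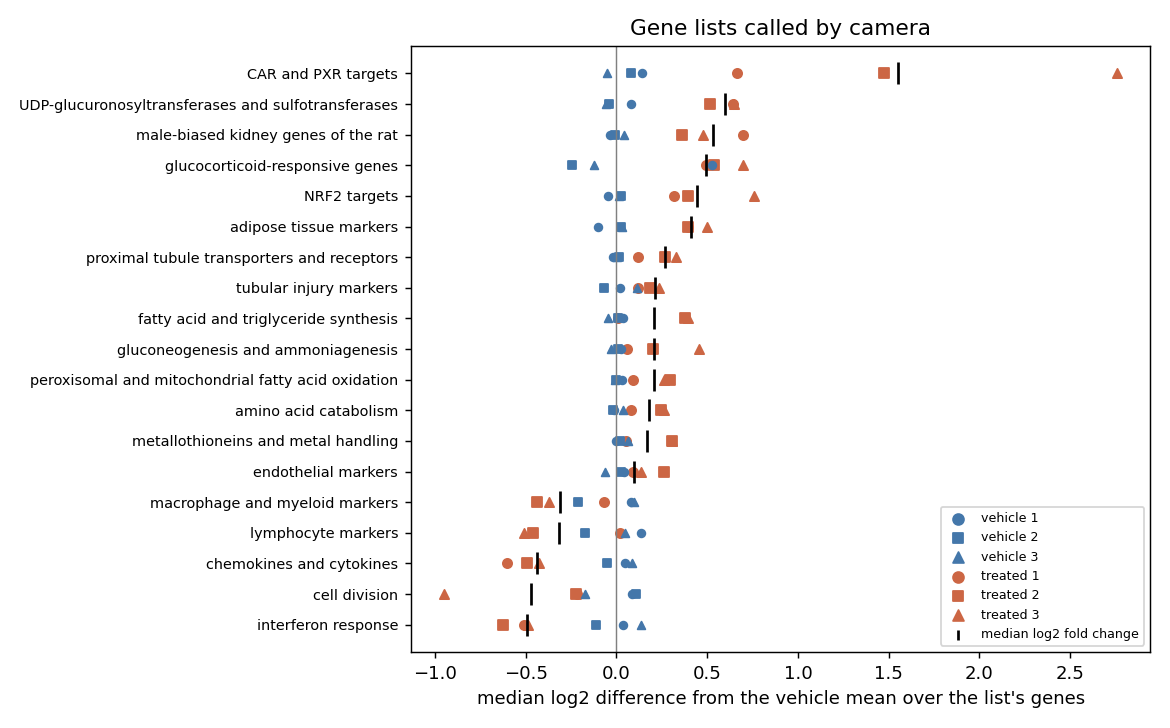
Median log2 difference from the vehicle mean over the genes of each of the 19 lists called by camera, with points for single arrays and a black mark for the median log2 fold change. CAR and PXR targets had medians of 0.67, 1.47 and 2.76 in treated 1, 2 and 3, and the interferon list had -0.51, -0.63 and -0.49.

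Tubular injury markers as a list had a median of 0.21 (camera adjusted p = 0.037, lost at adjusted p = 0.56 with an estimated correlation) and 0.12 with slide as a block, where the call ended. The call also ended without vehicle 2 (0.16), without treated 1 (0.28), without treated 3 (0.10) and with median centring (0.23). Of 35 members only Igfbp1 (1.5037, SE 0.25) rose adjusted over the list alone. Gdf15 had the largest difference of the list (1.97, SE 0.41, and 1.11 with slide as a block). It fell just short adjusted over the list alone (limma adjusted p = 0.053). The injury markers Havcr1 (-0.16, SE 0.25), Lcn2 (0.70, SE 0.41), Clu (-0.65, SE 0.20) and Spp1 (0.20, SE 0.21) did not pass, with adjusted p-values from 0.173 to 0.748. Havcr1, Lcn2 and Spp1 differed by less than 2 standard errors. Metallothionein and metal handling genes (median 0.17), endothelial markers (0.10) and adipose markers (0.41) were called higher at camera adjusted p-values of 0.026, 0.021 and 0.0034. These were lost at adjusted p = 0.46, adjusted p = 0.58 and adjusted p = 0.37 with an estimated correlation, and with slide as a block the medians were 0.06, 0.09 and 0.40 and all 3 calls ended. The metallothionein call also ended without vehicle 1 (0.18) or treated 3 (0.16), and the endothelial call without vehicle 3 (0.10) or treated 3 (0.09). With slide as a random block both the metallothionein (0.14) and the endothelial (0.11) call ended, and with the liver score as a covariate the endothelial call ended (0.08). Without treated 1 the metallothionein and endothelial medians were 0.28 and 0.19, and without vehicle 1 the endothelial median was 0.16. In all, 14 of 41 lists were called higher and 5 lower, and 0 were called with an estimated correlation (lowest adjusted p = 0.37). The estimated correlation was 0.016 for conjugating enzymes and -0.044 for adipose markers, near or below the preset 0.01, and both calls were lost all the same. A call lost under this setting thus does not by itself show that the members varied together. With fry, 6 of the 19 calls held: NRF2 targets, conjugating enzymes, adipose markers, male-biased genes, interferon response and chemokines. AhR targets, not called by camera, were called higher with fry. Ribosomal protein genes, a control list, had a median of 0.01 and were not called, and their sign changed under quantile normalization.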

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

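A floor on dim values, an adjusted p under 0.1 and the liver transcript score were chosen after seeing the data. The counts of called probes depended on the setting, and the cause was not tested unless stated. Against 1 probe higher and 2 lower, there were 96 and 40 with normexp and 109 and 47 with an intensity trend and robust variance. There were 0 and 1 without a filter, 0 and 0 with only probes above background on all arrays, 0 and 1 with slide as a fixed block and 0 and 0 on the slide with both groups alone. An adjusted p under 0.01 gave 0 and 1, a floor on dim values 0 and 0, the liver score 4 and 3, and an adjusted p under 0.1 gave 379 and 288. Leaving out each array in turn gave 0 to 1469 probes higher and 0 to 2838 lower. The highest counts, without treated 1, compare groups that coincide with slide 1 and slide 2. Without vehicle 2 or treated 2 the test called 0 probes, with 4954 and 5948 at an unadjusted p under 0.05. Without vehicle 1 there were 3 and 1, without vehicle 3 there were 2 and 2, and without treated 3 there were 1 and 1. With the replicate block 0 probes were called higher and 0 lower, with 7240 at an unadjusted p under 0.05. No pairing by number was seen, as same-numbered arrays' deviations from their group means correlated at -0.21, 0.01 and -0.16. With 3 arrays per group these values cannot exclude a pairing. The 14 lists higher and 5 lower became 12 and 3 with slide as a fixed block or on the shared slide alone, 5 and 2 with fry, and 0 and 0 with an estimated correlation. Leaving out an array gave 12 to 16 higher and 3 to 6 lower. The fixed block ended 9 list calls (fatty acid and triglyceride synthesis, tubular injury, macrophage, lymphocyte, cell division, proximal tubule transporters, metallothionein, endothelial and adipose) and added 5, AhR targets, adrenal markers, blood cell markers and extracellular matrix higher and lysosome genes lower.

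Direction changed for 2 called lists, macrophage and lymphocyte markers, and for lists and genes that were not called, and a list's test direction can differ from the sign of its median. With slide as a fixed block the medians were macrophage markers -0.066, lymphocyte markers 0.018, respiratory chain -0.038, vitamin D and calcium genes -0.24, clock genes -0.064, podocyte markers -0.034, distal tubule markers -0.20 and ribosomal proteins -0.030, and the genes Cdkn1c -0.039, Havcr1 0.22 and Spp1 -0.22. On the shared slide alone the values were the same, except distal tubule markers at -0.17. With slide as a random block they were vitamin D and calcium genes -0.16, clock genes -0.049, distal tubule markers -0.15, ribosomal proteins -0.021 and Havcr1 0.0088. Normexp gave clock genes -0.057 and distal tubule markers -0.10, quantile normalization gave respiratory chain -0.021 and ribosomal proteins -0.053, and median centring gave clock genes -0.022. Ribosomal proteins had 0.0094 without a filter and with fry, and clock genes -0.037 with fry. The liver score gave vitamin D and calcium genes -0.069, clock genes -0.058 and ribosomal proteins -0.0011. Leaving out an array, medians ranged from -0.073 to 0.012 for unfolded protein genes, -0.056 to 0.12 for heat shock genes, -0.11 to 0.13 for vitamin D and calcium genes, -0.062 to 0.033 for clock genes, -0.095 to 0.071 for medulla markers and -0.021 to 0.011 for ribosomal proteins, and Havcr1 from -0.34 to 0.11. Signal over background limits Kcna4, the dim Nabp1 probe and Cyp2b1, Cyp2b12 and Cyp2b21 among the Cyp2b genes to lower bounds.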

Other observations

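All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays.

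The treated arrays' higher CAR and PXR signal was set against slide, and against liver RNA. Treated 1, which shared slide and scan with the vehicle arrays, had a list median of 0.67, against at most 0.21 for a vehicle array, and the list call held with slide as a block. With the brightest probes chosen on that slide, which replaced the probe of 1 gene, the values were 0.34 and 0.19, under a 2-fold margin, and only 1 treated array shared the slide, so slide as the whole cause stays open. The test first asked only for a 2-fold margin with the original probes, which was met. The conditions on probes and on the number of treated arrays were added after these values were seen and changed the verdict from evidence against slide to an open question. The median excess of 1.60 of treated 2 and 3 over treated 1 (95% bootstrap interval over genes 0.42 to 2.28) cannot be told apart from slide, since slide 2 held only these animals. A first test asked only whether treated samples held more liver RNA. The 17 picked liver transcripts had a median difference of 0.55 (95% bootstrap interval over genes 0.37 to 0.77) against 3.52 for the 12 list members above 1. On these 6 arrays that is too little to be the whole cause for those members. The 12 were chosen for a difference above 1, and the interval does not measure the spread between animals. The median of the 17, relative to each gene's mean over the arrays, was 0.98, 0.03 and -2.10 in vehicle 1, 2 and 3. It was -0.81, -0.08 and 1.76 in treated 1, 2 and 3. The first test could not see liver RNA present in both groups. Alb spanned 3.77 log2 units among vehicle arrays and 2.66 among treated ones. A liver responding to the compound could then carry its P450 transcripts into every treated sample.

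The added test compared treated 3 with treated 1, which differed by a median of 3.24 (2.76 to 3.71) for those 12 members and 2.66 for the liver transcripts. The list members thus varied at least as much as the liver transcripts, with the liver value just below the interval, so induction in liver, carried as RNA traces, and induction in kidney may both contribute and these data do not decide. Treated 2, also on slide 2, exceeded treated 1 by a median of 0.86 for the liver transcripts. Its excess was 1.64 for Cyp2b1, 1.30 for Cyp2b2 and 1.33 for Ugt2b1, but 0.61 for Por and 0.15 for Gadd45b. The liver list held 31 genes, of which 29 were tested and 5 also stood in the fixed lists, and kidney itself expresses several of them. With the liver score as a covariate the list median was 1.30, but this removes only the share of liver RNA and not a response of the liver. Under the same covariate Cyp3a23-3a1 gained a call (5.53, adjusted p = 0.0092) and Dhcr7 lost its call (adjusted p = 0.066) at a log2 fold change of 1.40, as without it. A measurement in perfused or microdissected cortex would be needed. Gadd45b, Dhcr7 and the interferon genes did not vary with the liver transcripts in this way.

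The lower interferon and chemokine signal had medians of -0.51 and -0.60 in treated 1, against at most 0.20 and 0.13 in size for vehicle arrays, and the calls held with slide as a block. This met the 2-fold margin, which at first counted against slide as the whole cause, but it rests on 1 treated array, so under the condition added later slide stays open here too. A smaller share of leukocytes would lower their markers at least as far. Over all arrays 42 macrophage and lymphocyte markers lay above 47 interferon and chemokine genes by 0.14 (0.05 to 0.38), but by array the difference was 0.53 in treated 1 (0.35 to 0.73), 0.14 in treated 2 (-0.13 to 0.40) and -0.01 in treated 3 (-0.22 to 0.17). The markers thus lay about as low as these genes in treated 2 and 3, and 1 array alone excludes nothing. Vehicle 2 itself had -0.32 for macrophage and -0.26 for lymphocyte markers against the other vehicle arrays. A smaller share of leukocytes and a lower interferon and chemokine response both stay open. The test first used all arrays and treated 1 and counted against a smaller share. The condition on each treated array was added after the values were seen.

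The first principal component (46.2% of variance) placed vehicle 1, 2 and 3 at -40.6, -39.2 and -36.9. Treated 1 lay at 4.35, and treated 2 and 3, on slide 2, at 44.8 and 67.5, so both the groups and the slides separated on it. A second axis of variation crossed the groups. The second principal component (22.8% of variance) placed vehicle 1 at 42.1, vehicle 3 at -24.7 and treated 1 at -51.6. The slide 1 arrays spanned 93.7 on it and enclosed the 2 arrays of slide 2, which lay 11.5 apart. Slide thus cannot account for the spread among the slide 1 arrays. Components are uncorrelated over the arrays, so with the slides apart on the first, the second had little room to separate them. Their overlap on the second component therefore decides nothing further about slide. Slco1a1, an organic anion transporter of the straight segment (S3), had -1.23, 1.37 and 2.26 in vehicle 1, 2 and 3, and 3.59, 2.00 and 2.27 in treated 1, 2 and 3. A different share of straight proximal tubule in the dissected pieces is a candidate explanation. In vehicle 1 against the other vehicle arrays, 11 S3 genes lay below 13 S1 and S2 genes by -0.47 (-2.47 to -0.22), short of the 0.5 set for the test. In treated 1 against the other treated arrays, a contrast for which no bound was set, S3 genes lay above S1 and S2 genes by 0.82 (0.51 to 1.36), which goes with this explanation. It stays open, since the contrast that had a bound missed it. S3 genes made up 3 of the 14 male-biased genes, whose median was 0.53 with them and 0.26 without, so part of that median is open to the same explanation. They made up 5 of the 46 proximal tubule genes, whose median was 0.27 with them and 0.23 without, so they did not carry that median. A median over 46 genes moves little without 5 of them, and the list test was not rerun, so the explanation stays open for that call.

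Grouping by chance was examined over the 10 splits of the 6 arrays into 3 and 3, which cannot give a share under 0.05. The real split called 3 probes and the highest other 4, and 2 of the 10 splits, the real one included, called at least as many as the real one. For gene lists the real split called 19 and the others 4 to 20, again with 2 of the 10 splits, the real one included, at least as high. Every split thus called some lists, so a camera call at the preset correlation does not by itself mark the treatment. The split with 4 probes set vehicle 1 with treated 2 and 3, and the split with 20 lists set vehicle 1 and vehicle 3 with treated 1. By the count of probes at an unadjusted limma p under 0.05, the real split stood highest, with 8377 against 619 to 3499 in the others. Next came the other splits that kept treated 2 and 3, both on slide 2, on the same side, with 3499, 2510 and 2106. Splits that separated these arrays had 619 to 1630. The real split also keeps them together, so this ranking cannot tell treatment from slide.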
